A study of Mus musculus with 6 samples.

How the data were processed

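The series holds 6 RNA-seq libraries of flow-sorted cells from the subependymal zone of gfap:GFP mice, 3 after vehicle and 3 after a miR-204 antagomir. Per the labels' protocols, RNA was isolated with a PicoPure kit, cDNA was made with the SMART-Seq v4 low-input kit, which does not mark strand, and 100 bp paired-end reads were sequenced on an Illumina HiSeq. Groups were taken from the labels' treatment group and replicate numbers from the labels. The labels' treatment field names the antagomir for all 6 samples, so it was not used for grouping.

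The submitters' processing notes name kallisto, sleuth and the genome build mm10, with versions not given in the sources used here. The deposited estimated counts (expected counts) are kallisto's share of fragments per transcript, per the file headers, and they are not normalized. The deposited TPM values are the same estimates divided by effective transcript length and scaled to the same total in every library, per the file headers. kallisto divides reads among similar transcripts by a model, so genes with near-identical copies or pseudogenes are uncertain.

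Of 99567 transcripts, 98294 (98.7%) matched a transcript of GENCODE M21 (GRCm38) by identifier, and the other 1273, which held 0.524 to 0.586% of each library's counts, were left out. Estimated counts were summed over the transcripts of each gene and rounded to whole numbers, for 32564 genes. Library totals were 14866453 to 19694409 estimated counts. The libraries were compared for identity by a chi-square per gene, which was 23.8 to 100.4 over the 15 pairs, so no pair differed by as little as sampling noise.

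Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with its defaults including a minimum count of 10, robust quasi-likelihood test, group as the only term, all 6 libraries), with Benjamini-Hochberg adjustment over 15012 genes and a threshold of 0.05. The common biological coefficient of variation was 36.2%. CPM values use the TMM-scaled library sizes, and scores and principal components use log2 CPM with a prior count of 2. The test was tried on simulated counts with the means and spread of these libraries, in which 50 genes each were changed by 1.5, 2, 4 and 8-fold. It recovered 1, 5, 34 and 43 of them and made 5 false calls among 14739 genes tested in that step.

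Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with the correlation estimated per list, and with fry, each adjusted over 28 lists. fry asks whether a list's genes move on balance one way and does not compare them with other genes. The lists were quiescent neural stem cell, activated neural stem cell and progenitor, neuroblast, mature neuron, astrocyte, reactive astrocyte, ependymal cell, choroid plexus epithelium, oligodendrocyte, oligodendrocyte precursor, microglia and macrophage, endothelial cell, pericyte and fibroblast, blood and leukocyte, cell cycle, interferon response, immediate early and dissociation stress, BMP and TGF-beta signalling, Notch signalling, Wnt signalling, fatty acid oxidation, glycolysis, oxidative phosphorylation, ribosomal protein, mitochondrially encoded, p53 response and apoptosis, unfolded protein response, and reported miR-204 targets. Lists were written from general knowledge, and some share members, such as 4 genes between the neuroblast and reported target lists. A library's score for a list is the median over members of log2 CPM minus the mean of the 6 libraries, compared between groups with an exact two-sided permutation test.

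Predicted targets were protein-coding genes with an 8mer or 7mer-m8 match to miR-204-5p in the annotated 3′ UTR of their most abundant transcript, and genes without an annotated 3′ UTR were not searched. They were compared with 10000 random sets drawn in 10 bins each of 3′ UTR length and expression and with 33 control seeds. These were the other orders of the seed match's bases, less AAGGGAA, which is the 7mer-A1 match of miR-204-5p.

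The groups, the comparisons with their tests, the lists and the alternatives were fixed before the data were examined. The exceptions are 2 alternatives named as added, the tests that the closing observations name as chosen later, a second list of microglia genes, and the genes named below as outside the rule. The rule for naming genes took the 12 genes with the smallest p past the threshold in each direction or, where fewer than 10 passed, the 10 with the smallest p, as values. Gm and Rik names and pseudogenes were left out. It also took up to 4 tested members per list with the smallest p, and always Trpm3, Meis2, Sox11, Dcx, Gfap, Egfr, Mki67 and Ttr, while some genes it took are not reported here. Csf1r and the Y-linked genes other than Eif2s3y lie outside the rule and were chosen after their values were seen. Their X-linked partners were chosen after the Y-linked values, and before their own, were seen. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on log2 TPM with a pseudocount of 1 or 0.1, length-scaled TPM, a test per transcript, other filters and thresholds, the replicate number as a block, leaving out gene classes, leaving out each library in turn, other site classes and the longest 3′ UTR.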

Results

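RNA sequencing was used to measure transcript levels in cells taken as quiescent neural stem cells (qNSCs). These are the mostly non-dividing stem cells of the adult subependymal zone beside the lateral ventricles of the brain. The cells were sorted by flow cytometry from gfap:GFP mice, which carry green fluorescent protein under the promoter of the astrocyte and stem cell gene Gfap. Transcripts of other cell types, such as the myelin gene Mbp, were also present, so the identity of the sorted cells was not established here. The mice were 3 months old, and the cells were taken 3 days after an injection into the ventricles. The injection held either artificial cerebrospinal fluid (vehicle, 3 libraries) or an antagomir, a modified oligonucleotide that binds and blocks a microRNA, directed against miR-204 (3 libraries). By its title the series concerns miR-204 released by the choroid plexus, the tissue that secretes cerebrospinal fluid, and the number of neural stem cells. The comparison of antagomir with vehicle asks which transcripts of the sorted cells differed after the antagomir. The labels name no control oligonucleotide, so an effect of the injected oligonucleotide itself cannot be told apart from an effect of blocking miR-204. The level of miR-204 was not analysed here.

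Each library held 14866453 to 19694409 estimated counts and had 17180 to 17975 genes with at least 1 count. Levels are given in CPM, counts scaled to library size. A floor of 3 counts corresponded to 0.153 to 0.203 CPM, and such floors and intervals cover counting error only. Levels are mean CPM ± SD over n = 3 libraries per group, and fold changes are log2 values of antagomir over vehicle from edgeR. The labels do not say whether the replicates came from separate animals or pools of animals, so the p-values measure only the spread between these samples, which may be technical. No exact two-sided test of 3 against 3 libraries can give a p below 0.1, and for the list scores the exact permutation p adjusted over the 28 lists was at least 0.7.

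Genes of cell division, of neuroblasts (the migrating immature neurons that arise from these stem cells) and of oligodendrocyte precursors were higher on balance in the antagomir libraries, while genes of the interferon response, microglia and astrocytes were lower on balance. The median log2 fold change was 0.67 over 40 cell cycle genes, 0.66 over 38 neuroblast genes and 0.44 over 19 oligodendrocyte precursor genes. It was -1.24 over 29 interferon response genes, -1.85 over 30 microglia and macrophage genes and -0.22 over 24 astrocyte genes. Of 28 gene lists, 15 passed an adjusted p of 0.05 with camera at its preset correlation between genes, 5 of them higher and 10 lower. With an estimated correlation 0 of the 15 passed, and with fry 0 passed. At an unadjusted p under 0.05 there were 17 lists with the preset correlation and 0 with the estimated one. Without vehicle replicate 1, 8 lists passed with the preset correlation. The microglia and macrophage median then turned to 0.13 (camera adjusted p = 0.738), and the interferon median was -0.37. Without antagomir replicate 1 the neuroblast median was 0.085 and that list did not pass (camera adjusted p = 0.102).

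**Figure D1:**
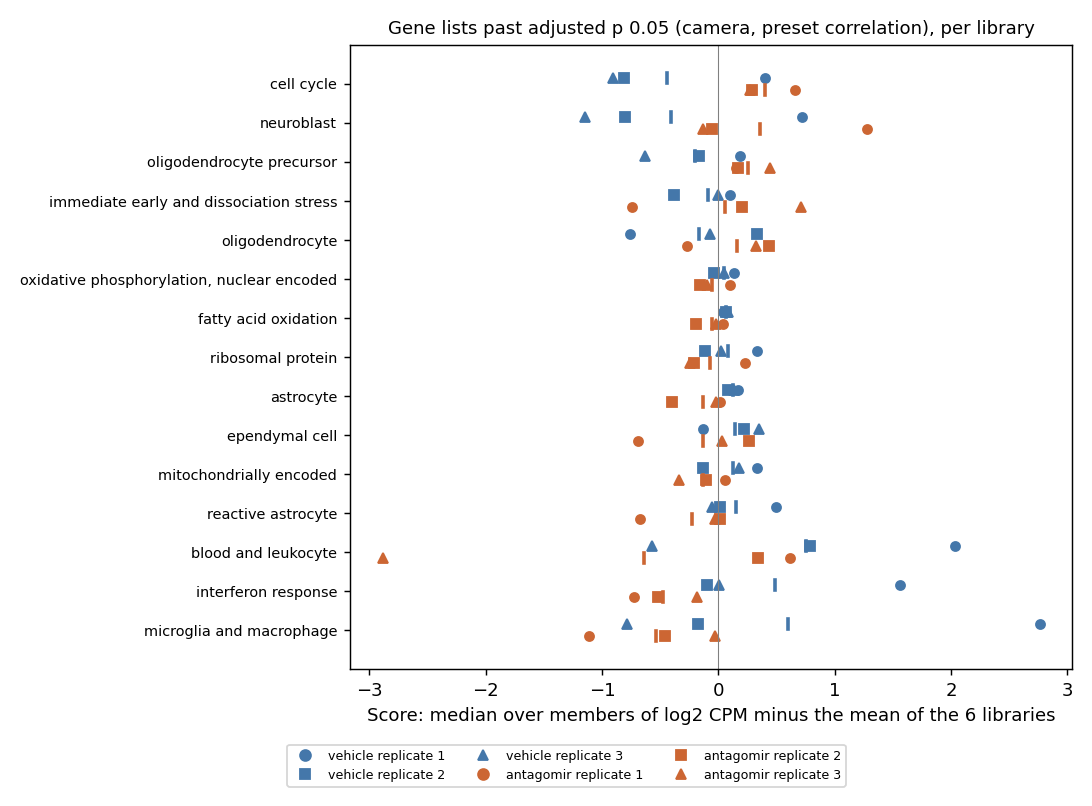
Score of each library (x axis, median over a list's members of log2 CPM minus the mean of the 6 libraries) for the 15 gene lists past an adjusted p of 0.05 with camera's preset correlation (y axis), with vehicle in blue, antagomir in orange, marker shape for the replicate number and a vertical bar for each group mean. Vehicle replicate 1 stood at 2.76 for microglia and macrophage genes and 1.56 for interferon genes, and at 0.40 for cell cycle genes, inside the antagomir range of 0.27 to 0.66.

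For single genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 15012 tested genes, and the smallest adjusted p was 0.949. At an unadjusted p under 0.05 there were 616 genes, 327 higher and 289 lower, where 750.6 are expected by chance. The groups did not overlap in 10.5% of the genes (761 higher, 818 lower), and chance gives 10%. DESeq2 called 1 gene, Frmpd4, a scaffold protein of synapses, with a log2 fold change of 6.39 and an adjusted p of 0.0214. Frmpd4 (ENSMUSG00000049176.14, chromosome X, 167471309 to 168577231 in GRCm38) had 232 counts in the antagomir libraries and 3 in the vehicle libraries, a ratio of 84.9 with a 95% counting interval of 28.7 to 415. Its levels in antagomir replicates 1, 2 and 3 were 10.9, 2.48 and 0.907 CPM. In simulated data with the spread of these libraries, edgeR recovered 10% of genes changed 2-fold, 68% of those changed 4-fold and 86% of those changed 8-fold. Most 2-fold differences were thus not detectable here. The simulated genes were drawn independently of each other and many were changed, so these shares may be too high for the real libraries.

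The 10 genes with the smallest p among those higher in the antagomir libraries were Tg, Fam83d, Frmpd4, Nacad, Magee2, Katnal1, Enpp6, Rusc2, Ihh and Depdc1b, and none of them passed edgeR's test. Fam83d, a spindle protein of dividing cells (ENSMUSG00000027654.2, chromosome 2, 158768093 to 158786637), measured 17.7 ± 1.96 CPM with vehicle and 31.6, 35.1 and 47.3 CPM in the antagomir libraries. Enpp6, a marker of newly forming oligodendrocytes, measured 18.9 ± 1.46 and 42.6 ± 15.1 CPM, and Rusc2 measured 151.5 ± 4.07 and 213 ± 6.44 CPM. Tg, the thyroglobulin gene, had 129 counts with antagomir and 2 with vehicle, a ratio of 70.8 with a counting interval of 19.2 to 591. Magee2 had 41 counts with antagomir and 0 with vehicle, at least 15.01-fold higher against the floor of 3 counts over the group. The 10 genes with the smallest p on the lower side were Herc6, D10Jhu81e, Paqr3, Gdnf, Tlr1, Ecm1, Eif2s3y, Pctp, Il1rn and Adgrb3, again with none past the test. Herc6, an interferon-induced gene (ENSMUSG00000029798.11, chromosome 6, 57581000 to 57664632), measured 44.3 ± 7.02 CPM with vehicle and 23.3 ± 2.64 CPM with antagomir. Gdnf, a neurotrophic factor, had 75 counts with vehicle and 2 with antagomir, a ratio of 34.1 with a counting interval of 9.13 to 287. Tlr1, a receptor of innate immunity, measured 3.63 ± 2.84 and 0.115 ± 0.149 CPM. Eif2s3y, a translation factor gene of the Y chromosome, measured 63.2 ± 13.2 and 34.5 ± 5.79 CPM, and the other Y-linked genes tested, Kdm5d, Uty and Ddx3y, had log2 fold changes of -0.77, -0.59 and -0.42 (named after their values were seen).

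In the cell cycle list 39 of 40 members had positive fold changes (camera adjusted p = 2.49e-18, adjusted p = 0.660 with an estimated correlation). Aurkb, a kinase of chromosome segregation, measured 11.04 ± 6.37 CPM with vehicle and 26.3 ± 0.708 CPM with antagomir. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, measured 17.2 ± 11.5 and 41.8 ± 9.47 CPM, and the spindle genes Kif20a and Nusap1 measured, with vehicle and antagomir, 22.2 ± 9.21 against 46.3 ± 10.5 CPM and 25.1 ± 16.0 against 54.9 ± 6.06 CPM. Of the members 14 lay under an unadjusted p of 0.05, all of them higher, 0 passed adjusted over the list alone, and 0 passed over all genes. The score of vehicle replicate 1 (0.40) lay inside the antagomir range of 0.27 to 0.66 and those of the other vehicle libraries were -0.81 and -0.91 (exact permutation p = 0.3). The list's median was 0.40 without vehicle replicate 2, 1.42 without vehicle replicate 1 and 0.54 without antagomir replicate 1 (adjusted p = 4.59e-12), and the list passed without any single library. Mki67, the gene of the proliferation antigen Ki-67, measured 39.2 ± 35.9 and 47.5 ± 3.89 CPM (log2 fold change 0.28, edgeR adjusted p = 0.963) and its fold change was -0.13 without vehicle replicate 2.

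In the neuroblast list 36 of 38 tested members had positive fold changes (camera adjusted p = 3.27e-09, adjusted p = 0.660 with an estimated correlation), with 0 members past the test adjusted over the list alone or over all genes. Stmn1, a microtubule regulator, measured 515 ± 168 CPM with vehicle and 853 ± 286 CPM with antagomir. The olfactory interneuron factor Sp8 measured 3.71 ± 4.29 and 14.2 ± 11.4 CPM, and Sox4, a transcription factor of immature neurons, measured 243 ± 121 and 411 ± 217 CPM. Dcx (doublecortin, ENSMUSG00000031285.14, chromosome X, 143855842 to 143933311) measured 61.5 ± 69.8 and 132 ± 122.9 CPM, of which vehicle replicate 1 had 142 and antagomir replicate 1 had 274, against 17.4 to 61.1 CPM in the other libraries. Without antagomir replicate 1 the list's median was 0.085 with a camera adjusted p of 0.102, so the call ended. The fold change of Dcx was then -0.011. The median was 1.32 without vehicle replicate 1 and 0.41 without vehicle replicate 3. The list of activated stem cells and progenitors did not pass (19 of 25 members positive, median 0.21, camera adjusted p = 0.0634). It passed without vehicle replicate 1 (median 0.43, adjusted p = 0.00294) and without antagomir replicate 2 (0.40, adjusted p = 0.00335), and its median was 0.047, 0.092 and 0.11 without antagomir replicate 1, vehicle replicate 2 and vehicle replicate 3. In it Insm1 measured 22.8 ± 15.9 and 53.5 ± 20.7 CPM, and the growth factor receptor gene Egfr 59.0 ± 11.97 and 41.7 ± 2.52 CPM.

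**Figure D2:**
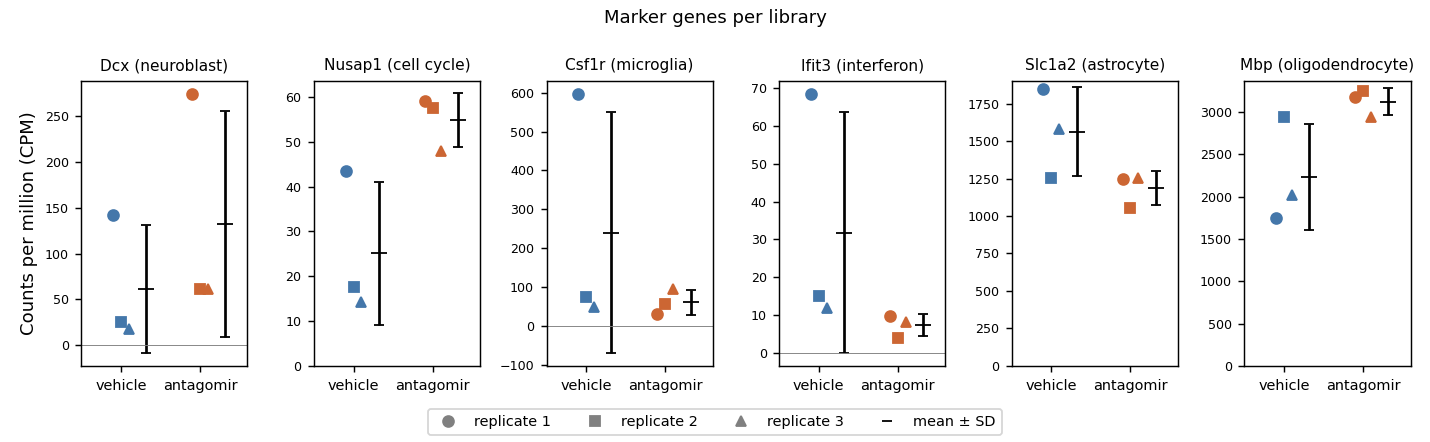
CPM (y axes, a separate scale in each panel) of 6 marker genes in each library by group (x axes), with points for the libraries, marker shape for the replicate number and black bars for the mean ± SD of 3 libraries. Vehicle replicate 1 held 596 CPM of Csf1r and 68.5 CPM of Ifit3, above the other 5 libraries, and Dcx was highest in antagomir replicate 1 and vehicle replicate 1.

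Interferon response genes had negative fold changes in 27 of 29 tested members (camera adjusted p = 2.73e-15, adjusted p = 0.660 with an estimated correlation). Of these genes 16 lay under an unadjusted p of 0.05, with 0 past the test adjusted over the list alone or over all genes. B2m, the light chain of class I major histocompatibility molecules, measured 111 ± 95.8 CPM with vehicle and 34.8 ± 2.98 CPM with antagomir, Ifit3 measured 31.8 ± 31.8 and 7.29 ± 2.96 CPM, and the interferon signalling factor Irf9 measured 38.1 ± 22.4 and 17.4 ± 1.90 CPM. Vehicle replicate 1 carried the highest levels, with 68.5 CPM of Ifit3 against 14.9 and 11.9 CPM in the other vehicle libraries. The scores of the groups did not overlap (exact permutation p = 0.1, the smallest this design allows). The same held for the astrocyte, fatty acid oxidation and glycolysis lists, where chance gives 10% of lists. Without vehicle replicate 1 the interferon median was -0.37 (camera adjusted p = 0.00204). Microglia and macrophage genes had negative fold changes in 28 of 30 tested members (camera adjusted p = 4.07e-08, adjusted p = 0.660 with an estimated correlation), again with 0 past the test adjusted over the list alone or over all genes. The complement gene C1qb measured 63.9 ± 83.9 and 9.39 ± 4.68 CPM, the protease gene Ctss 102 ± 139 and 18.9 ± 6.85 CPM, and the myeloid transcription factor gene Spi1 10.1 ± 9.31 and 2.97 ± 1.07 CPM. Vehicle replicate 1 had 161 CPM of C1qb against 20.9 and 10.3 CPM in the other vehicle libraries. Without vehicle replicate 1 the direction turned and the call ended, with a median of 0.13 and a camera adjusted p of 0.738.

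Reactive astrocyte genes were lower on balance (19 of 25 tested members, median -0.29, camera adjusted p = 0.00288, adjusted p = 0.660 with an estimated correlation). The interferon-inducible GTPase gene Gbp2 measured 49.5 ± 7.07 CPM with vehicle and 29.3 ± 5.30 CPM with antagomir, the cytokine receptor gene Osmr 3.16 ± 1.25 and 0.742 ± 0.292 CPM, and the class I gene H2-D1, which the interferon list also holds, 265 ± 130.1 and 148 ± 17.4 CPM. The call ended without vehicle replicate 1 (median -0.078, adjusted p = 0.470) and without antagomir replicate 1 (median -0.19, adjusted p = 0.155). The median was -0.56, -0.58 and -0.55 without vehicle replicate 3, antagomir replicate 2 and antagomir replicate 3. Blood and leukocyte genes were lower in 6 of 8 tested members (median -0.97, camera adjusted p = 0.0314, adjusted p = 0.660 with an estimated correlation). They were led by red cell genes, with 211 ± 181 and 75.1 ± 62.1 CPM of the haemoglobin gene Hba-a1, whose counts can be shared with a near-identical copy. That call ended without vehicle replicate 1 (median -0.54, adjusted p = 0.516), vehicle replicate 2 (median -0.98, adjusted p = 0.105) or antagomir replicate 3 (median -0.46, adjusted p = 0.521). It also ended with no filter on low counts (median -0.42, adjusted p = 0.121). In both lists 0 members passed adjusted over the list alone or over all genes.

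Astrocyte genes were lower in 21 of 24 members (camera adjusted p = 2.41e-06, adjusted p = 0.660 with an estimated correlation), and their scores did not overlap between the groups (exact permutation p = 0.1). The amino acid transporter gene Slc7a10 measured 285 ± 18.3 CPM with vehicle and 213 ± 25.3 CPM with antagomir, the claudin gene Cldn10 264 ± 32.8 and 186 ± 34.1 CPM, the calcium-binding protein gene S100b 97.3 ± 11.1 and 74.1 ± 7.72 CPM, and the glutamate transporter gene Slc1a2 1563 ± 297 and 1186 ± 115 CPM. The median was -0.11 without antagomir replicate 2, and the list passed without any single library. The quiescent stem cell list, measured in the same cells, did not pass (21 of 32 members negative, median -0.11, camera adjusted p = 0.0549). It passed without antagomir replicate 1 (median -0.14, adjusted p = 0.000210) and without antagomir replicate 3 (-0.15, adjusted p = 0.0244), and its sign turned without antagomir replicate 2 (0.032). With a filter at a mean count of 50 its adjusted p was 0.0414. In it Hopx measured 48.8 ± 6.82 and 30.8 ± 4.86 CPM, Fabp7 67.8 ± 22.0 and 44.0 ± 3.94 CPM, S1pr1 1062 ± 58.0 and 852 ± 139.6 CPM, and Klf9 120.4 ± 13.3 and 149 ± 10.95 CPM. Gfap itself measured 370.4 ± 184 and 237 ± 57.1 CPM (edgeR adjusted p = 0.949). Ependymal genes, of the ciliated cells that line the ventricle, were negative in 30 of 30 members (median -0.23, camera adjusted p = 2.09e-05, adjusted p = 0.675 with an estimated correlation), with the cilia genes Tekt1 at 133 ± 21.01 and 93.5 ± 22.96 CPM and Tmem212 at 357 ± 45.7 and 272 ± 73.4 CPM. Without antagomir replicate 1 the ependymal median was 0.031 and the adjusted p 0.889, so the call ended. It was -0.35, -0.090 and -0.43 without vehicle replicate 1, vehicle replicate 3 and antagomir replicate 2. In these 3 lists 0 members passed adjusted over the list alone or over all genes.

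Oligodendrocyte genes had positive fold changes in 28 of 28 members (median 0.31, camera adjusted p = 8.23e-06, adjusted p = 0.660 with an estimated correlation). The myelin gene Mbp measured 2233 ± 625 CPM with vehicle and 3121 ± 159 CPM with antagomir, and Mobp measured 811 ± 254 and 1070.4 ± 70.6 CPM. Myelin transcripts were abundant in every library, with 1741 to 3245 CPM of Mbp. Vehicle replicate 1 had the lowest oligodendrocyte score (-0.76), and without it the call ended (median 0.063, adjusted p = 0.738), and the median was 0.59 without vehicle replicate 2 and 0.19 without antagomir replicate 2. Oligodendrocyte precursor genes were higher in 15 of 19 tested members (camera adjusted p = 7.20e-05, adjusted p = 0.660 with an estimated correlation), with Gpr17, a receptor of committed precursors, at 22.3 ± 11.1 and 52.3 ± 21.8 CPM and the growth factor receptor gene Pdgfra at 22.6 ± 18.0 and 49.7 ± 22.8 CPM. The precursor median was 0.81 without vehicle replicate 1, and the list passed without any single library. In both lists 0 members passed adjusted over the list alone or over all genes.

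Mitochondrially encoded transcripts were lower in 13 of 13 tested members (median -0.24, camera adjusted p = 1.81e-05, adjusted p = 0.660 with an estimated correlation), with mt-Co1 at 5989 ± 1028 and 4508 ± 507 CPM and mt-Co3 at 6637 ± 952 and 5238 ± 322 CPM. The call ended without vehicle replicate 1 (median -0.15, adjusted p = 0.0691), and the median was -0.37 without vehicle replicate 2 and -0.15 without antagomir replicate 3. Nuclear genes of oxidative phosphorylation were lower in 48 of 54 members by small amounts (median -0.088, camera adjusted p = 0.00416, adjusted p = 0.687 with an estimated correlation), and ribosomal protein genes in 67 of 78 (median -0.14, camera adjusted p = 0.000365, adjusted p = 0.687 with an estimated correlation). Counts of ribosomal protein genes are uncertain because their many pseudogenes share reads with them. Both calls ended without vehicle replicate 1 (medians -0.029 and -0.0060, adjusted p = 0.252 and 0.516), antagomir replicate 2 (medians -0.015 and -0.0715, adjusted p = 0.399 and 0.200) or antagomir replicate 3 (medians -0.046 and -0.017, adjusted p = 0.145 and 0.247). The medians were -0.18 and -0.30 without antagomir replicate 1. The ribosomal protein median was -0.21 without vehicle replicate 2. Fatty acid oxidation genes were lower in 19 of 27 tested members (median -0.10, camera adjusted p = 0.0271, adjusted p = 0.660 with an estimated correlation), led by the acyl-CoA dehydrogenase gene Acads at 22.0 ± 1.73 and 12.8 ± 1.40 CPM. That call ended without any of the vehicle replicates (adjusted p = 0.0792, 0.117 and 0.107 for replicates 1, 2 and 3) and without antagomir replicate 2 (median -0.0021, adjusted p = 0.622). Immediate early and dissociation stress genes were higher in 25 of 36 tested members (median 0.34, camera adjusted p = 0.0263, adjusted p = 0.7503 with an estimated correlation). The transcription factor genes Jund, Jun and Egr1 measured 898 ± 27.3 against 1139 ± 101 CPM, 1953 ± 160.0 against 2714 ± 654 CPM and 1714 ± 141 against 2600.3 ± 940.4 CPM. That call ended without vehicle replicate 2 (median 0.21, adjusted p = 0.650), antagomir replicate 2 (median 0.31, adjusted p = 0.200) or antagomir replicate 3 (median 0.011, adjusted p = 0.146, with the direction of the test turned). The median was 0.53 without antagomir replicate 1. In these 5 lists 0 members passed adjusted over the list alone or over all genes.

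With all 6 libraries the other lists did not pass with camera, and 0 of their members passed adjusted over the list alone or over all genes. Their medians and adjusted p-values were 0.20 and 0.426 for mature neurons, -0.25 and 0.276 for endothelial cells, -0.073 and 0.702 for pericytes and fibroblasts, -0.041 and 0.639 for choroid plexus epithelium, and 0.029 and 0.175 for p53 response and apoptosis. They were -0.018 and 0.779 for BMP and TGF-beta signalling, -0.014 and 0.317 for Notch signalling, -0.010 and 0.561 for Wnt signalling, -0.10 and 0.276 for glycolysis, and -0.021 and 0.338 for the unfolded protein response. For BMP and TGF-beta signalling and for Wnt signalling the test and the mean (0.027 and 0.080) were on the positive side of 0 while the median was negative. For the unfolded protein response the mean (0.000563) was positive while the test and the median were negative. Leaving out a single library made 4 of these lists pass. Without antagomir replicate 3 these were mature neurons (median 0.34, adjusted p = 0.0132), endothelial cells (-0.48, adjusted p = 0.0244) and the unfolded protein response (-0.15, adjusted p = 0.00246). The p53 list passed without antagomir replicate 1 (0.12, adjusted p = 0.00973) and without vehicle replicate 3 (0.10, adjusted p = 0.0476). The endothelial median ran from -0.50 without vehicle replicate 3 to -0.056 without antagomir replicate 1, the p53 median was -0.0060 without vehicle replicate 1, and the glycolysis median was -0.020 without antagomir replicate 2. The Notch effector gene Hey2 measured 21.4 ± 3.58 CPM with vehicle and 12.2 ± 1.44 CPM with antagomir. Ttr, the main transcript of choroid plexus epithelium, was too low to be tested, with 34 counts over the 6 libraries, of which antagomir replicate 1 held 21.

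Trpm3, the gene whose intron holds miR-204 (ENSMUSG00000052387.16, chromosome 19, 22139046 to 22995410), measured 62.8 ± 14.9 CPM with vehicle and 60.9 ± 9.65 CPM with antagomir (log2 fold change -0.044, edgeR adjusted p = 0.988), and its sign turned without vehicle replicate 3 (0.18) or antagomir replicate 1 (0.079). Among genes reported elsewhere as miR-204 targets, 19 of 30 tested members had positive fold changes and the list did not pass (median 0.16, camera adjusted p = 0.189), with 0 members past the test adjusted over the list alone or over all genes. Without antagomir replicate 1 the median was 0.037. In the fit without both first-numbered libraries, chosen after the data were seen, it was 0.077 and the list passed with camera's preset correlation (adjusted p = 0.00725). Some members of this list, such as Tgfbr1 and Vim, held no seed match in the 3′ UTR searched. Others, such as Ephb2 and Meis2, held only the 7mer-A1 match, which the predicted targets below leave out. Creb1, with an 8mer seed match in its 3′ UTR, measured 53.2 ± 10.7 and 70.4 ± 20.2 CPM, and Ephb2 measured 5.83 ± 2.02 and 9.17 ± 0.921 CPM. Meis2 measured 111 ± 35.3 and 130.3 ± 61.9 CPM and Sox11, with an 8mer, 50.4 ± 33.3 and 64.2 ± 41.2 CPM. Their log2 fold changes of 0.23 and 0.35 were -0.24 and -0.31 without antagomir replicate 1.

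Predicted targets were taken as the 1763 of 13019 tested genes whose 3′ UTR holds AAAGGGA, the match to positions 2 to 8 of miR-204-5p, of which 760 hold the 8mer AAAGGGAA. Their median log2 fold change was 0.0376 above that of the other genes (0.0377 against 0.000127), and as a set they did not pass with camera's preset correlation (p = 0.2501). With an estimated correlation the same set had p = 0.0397, and fry gave p = 0.0407. Genes with a site have longer 3′ UTRs (median 2068 bases against 755), and among 10000 random sets matched on 3′ UTR length and expression the site genes' median stood at percentile 6.8. The central 95% of the random sets ran from 0.0344 to 0.0626. Of 33 control seeds made of the same bases in another order, 29 gave a larger difference than the miR-204 seed.

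**Figure D3:**
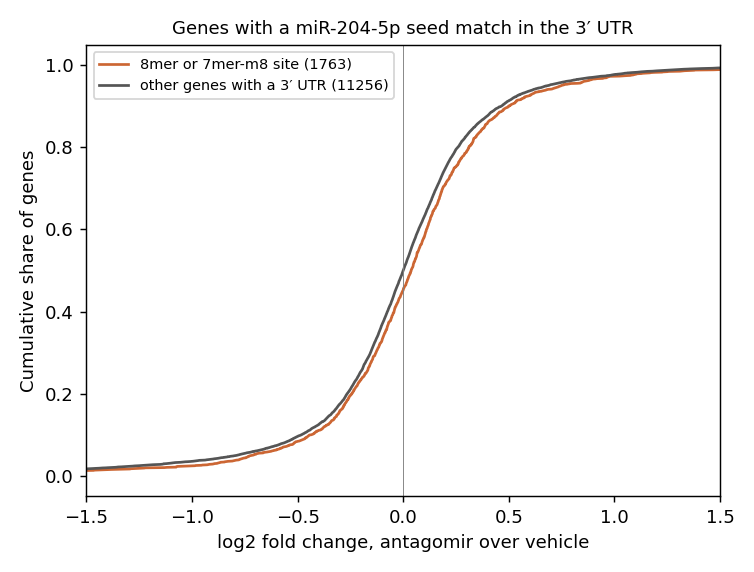
Cumulative share of genes (y axis) by log2 fold change of antagomir over vehicle (x axis, shown from -1.5 to 1.5) for the 1763 genes with an 8mer or 7mer-m8 seed match in the 3′ UTR (orange) and the other tested genes with a 3′ UTR (grey). The curves differ by 0.0376 at the median, less than for 29 of 33 control seeds.

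Over all tested genes, the first principal component of log2 CPM held 34.9% of the variance and set antagomir replicate 1 and vehicle replicate 1 apart from vehicle replicate 3, and its scores did not separate the groups (exact permutation p = 0.4). The second held 22.3% and set vehicle replicate 1 apart from antagomir replicate 1 (exact permutation p = 0.6). Pearson correlations across genes were 0.901 to 0.960 between libraries of the same group and 0.900 to 0.951 between libraries of different groups, and genes are not independent replicates.

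**Figure D4:**
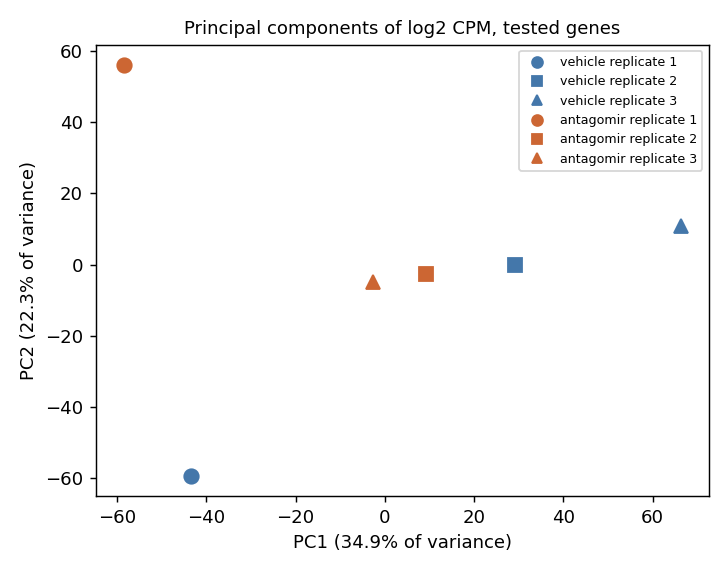
Scores of the 6 libraries on the first (x axis, 34.9% of variance) and second (y axis, 22.3% of variance) principal components of log2 CPM over the tested genes, with vehicle in blue, antagomir in orange and marker shape for the replicate number. Both first-numbered libraries lie far from the other 4.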

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

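The 2-against-2 fit without both first-numbered libraries and the fit with each library's microglia score as a covariate were chosen only after the data were seen. edgeR called 0 genes in each of its settings, including the looser threshold, and limma called 0. With DESeq2's Wald test 1 gene was called, higher (Frmpd4), and the cause was not tested. The smallest adjusted p over the settings other than DESeq2 lay between 0.0836 and 1.00. The number of lists past the threshold was 15 with the preset correlation, 0 with camera's estimated correlation, 0 with fry, and 8 to 15 without each replicate in turn. It was 16 in the 2-against-2 fit and 10 with the microglia covariate. The difference for predicted targets (0.0376) did not pass with the preset correlation in any setting run, passed with the estimated one, through the smaller correlation that was estimated, and was 0.0309 to 0.0523 over the other settings. Of 1674 comparisons of named genes with a setting 12 reversed, in 7 genes, and of 420 comparisons of lists 20 reversed (5 of them in called lists, which also lost their call, among them microglia with the covariate), 59 others lost their call and 19 gained one. The causes of these changes were not tested. Most genes were named for a small p in these same libraries, so the few reversals do not show that their directions hold. The setting with the looser threshold reuses the main fit, so no gene could reverse in it.

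The replicate numbers do not pair the samples by the labels, and deviations of same-numbered libraries correlated at 0.195, 0.0749 and 0.0275, with 3 of 6 samples correlating best with their own number. With the replicate block edgeR called 0 genes (1284 at an unadjusted p under 0.05) and 17 lists passed, now with quiescent neural stem cell, activated neural stem cell and reported miR-204 targets, while the immediate early list did not.

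Leaving out each replicate gave log2 ranges of -0.13 to 1.35 for Mki67, -0.087 to 0.29 for Kdm5c, -0.15 to 0.18 for Trpm3, -0.24 to 0.53 for Meis2, -0.31 to 1.03 for Sox11 and -0.011 to 2.66 for Dcx. List medians ranged from -2.30 to 0.13 for microglia, -0.094 to 0.36 for mature neuron, -0.24 to 0.10 for choroid plexus, -0.061 to 0.12 for BMP and TGF-beta, -0.26 to -0.00432 for pericyte, -0.15 to 0.014 for the unfolded protein response, -0.15 to 0.032 for quiescent stem cell, -0.10 to 0.028 for Notch, 0.011 to 0.53 for immediate early and -0.059 to 0.12 for Wnt. In the 2-against-2 fit, medians were 0.028 for choroid plexus, 0.32 for microglia, -0.055 for endothelial, -0.032 for reactive astrocyte and 0.045 for the unfolded protein response, with Csf1r at 0.30. The quiescent and activated stem cell, p53 and reported target lists passed in that fit with camera's preset correlation (adjusted p = 0.00146, 2.57e-05, 0.0375 and 0.00725). The activated list also passed with the covariate (0.0112) and with no filter (0.0368). With the microglia covariate they were 0.11 for microglia, whose own difference it removes by construction, and 0.078 for endothelial. Trpm3 was 0.074 with sample weights, 0.040 on log2(TPM + 1) with or without the filter and 0.041 with a pseudocount of 0.1. A simulated 2-fold change of single genes was recovered in 10% of cases at the depth, spread and number of these libraries, whose parts in this limit were not separated.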

Other observations

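The tests of the neuroblast scores and of the interferon genes of vehicle replicate 1 were chosen only after the results were seen. The second list of microglia genes was written after the fixed list was seen and before its own values were. The test of the X-linked partners was chosen after the Y-linked genes were seen and before the values of the partners were. The test of a wrong label was chosen after vehicle replicate 1 was seen to differ and before the positions were computed.

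Y-linked genes and their X-linked partners had fold changes of opposite sign. The 4 tested Y-linked genes were all lower in the antagomir libraries (log2 fold changes -0.87 for Eif2s3y, -0.77 for Kdm5d, -0.59 for Uty and -0.42 for Ddx3y, median -0.68), and their X-linked partners, which escape X inactivation, had positive values (0.45 for Eif2s3x, 0.33 for Ddx3x, 0.31 for Kdm6a and 0.10 for Kdm5c, the last -0.087 without vehicle replicate 2). None of the 8 passed edgeR's test (adjusted p 0.949 to 0.963), and Eif2s3y, Kdm5d and Eif2s3x did not overlap between the groups. All 6 libraries held Y-linked transcripts, with 27.8 to 78.2 CPM of Eif2s3y.

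A candidate explanation is a lower share of male cells in the antagomir libraries. The partners had to lie above 0 in that case, and their median was 0.32, the sign that this explanation needs. The SD over the 4 genes was 0.15, a spread between genes that does not measure error between the groups. The partners' standard errors were 0.18 to 0.21, and the value of Kdm5c (0.10) lay within its own. The explanation also needs the Y-linked genes to be lower by a common ratio, which was not tested. Their log2 fold changes ran from -0.87 to -0.42, with standard errors of 0.22 to 0.28. The labels give no sex, so an effect of the antagomir on these genes stays open, as untested.

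Between cell cycle and neuroblast scores of the 6 libraries, from lists that share 0 genes, Pearson's r was 0.912 (exact permutation p = 0.0153) and Spearman's rho was 1 (exact permutation p = 0.00278, the smallest that the 720 orders can give two-sided). The pair was picked after the scores of 28 lists were seen, and over all 378 pairs of lists 16 had an absolute r of this size or more. The Pearson permutation p adjusted over the pairs was 0.321. The smallest of any pair was 0.242, so with 6 libraries this adjustment let no pair pass and decides nothing about this one. Without antagomir replicate 1 and vehicle replicate 3, the libraries farthest from the median neuroblast score, r was 0.845 over 4 libraries. Without antagomir replicate 1 alone, the neuroblast median was 0.085 (adjusted p = 0.102) and the cell cycle median 0.54 (adjusted p = 4.59e-12), and in the 2-against-2 fit without both first-numbered libraries they were 0.75 (adjusted p = 7.40e-32) and 1.27 (adjusted p = 6.75e-51). All of these p-values are from camera at its preset correlation, which treats a list's genes as nearly independent. With the correlation estimated, run on all 6 libraries only, both lists had a camera adjusted p of 0.660. These values do not decide whether neuroblasts or their dividing precursors in the sorted cells could account for the cell cycle genes (Dcx was 274 CPM in antagomir replicate 1 and 142 CPM in vehicle replicate 1), and more division among the stem cells after the antagomir stays open as untested.

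In vehicle replicate 1, 29 of the 30 microglia markers of the fixed list were higher than in both other vehicle libraries, and so were 100% of a second list of 30 microglia genes outside the fixed lists (median log2 ratio 2.87), against 37.1% of all tested genes. The second list, many of whose genes other leukocytes share, had to show this if microglia were among the sorted cells. It was written after the fixed list was seen and was read in the same library, so it gives no independent support. Csf1r stood at 596 CPM in vehicle replicate 1 and at 32.5 to 96.6 CPM in the other 5 libraries, and Ctss at 262 against 14.2 to 26.8 CPM, although a sort on GFP should remove these cells. Interferon genes were also higher (28 of 29), and 3 of them exceeded the most raised microglia marker, too few to decide whether more microglia of the kind present in the other libraries may account for them. A wrong label could also be the cause. On 1104 genes picked from the other 5 libraries, vehicle replicate 1 had a median position of 0.105 (quartiles -0.17 and 0.44). The scale ran from the antagomir mean (0) to the other vehicle libraries (1). The other 5 libraries, treated likewise, stood at 0.306 to 0.472 from the opposite group. By this measure every library lay nearer the opposite group than its own. No gene passed the threshold between the groups, so the position cannot decide whether the label is wrong. Against a wrong label, all 4 tested Y-linked genes were higher in vehicle replicate 1 than in every antagomir library. Of the X-linked partners, Eif2s3x and Kdm6a were lower than in every antagomir library, while Kdm5c and Ddx3x lay within the antagomir range. The Y-linked genes were picked with vehicle replicate 1 counted as vehicle, so they do not decide the question, and the label was kept.

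The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other split also gave 0, a count that any of the 10 splits had to equal or exceed, so it tests nothing. For the gene lists 4 of 10 splits, the real one among them, gave at least the 15 of the real one, and the highest other had 16. For cell cycle genes the camera p was 8.90e-20 in the real split and 8.03e-21 in the split of vehicle replicate 1, antagomir replicate 1 and antagomir replicate 2 against the rest. At an unadjusted p under 0.05 the real split gave 616 genes, and the other splits gave 265 to 1852. The most came from the split of vehicle replicate 1, antagomir replicate 1 and antagomir replicate 3 against the rest. Some splits across the groups thus differed more than the groups did, and others differed less.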
